A study of Mus musculus with 4 samples.

How the data were processed

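RNA-seq was available for 4 libraries of GFP+ bone marrow cells, 2 Anp32b+/+ (wild type) and 2 Anp32b-/- (knockout), grouped by the genotype in the labels. Per the labels, total RNA was extracted with Trizol and libraries followed a standard protocol. The deposited files hold estimated read counts per gene symbol (expected counts), 1 file per library, with decimals. 64.5% to 65.6% of the values of a library were whole numbers. The submitters' processing notes name HISAT2 2.0.4, DESeq2 1.4.5 and the build GRCm38. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here, nor which reads of overlapping or near-identical genes were shared out.

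The files list 16613 symbols, of which 99.6% matched a RefSeq gene of GRCm38.p6, the same build. Coordinates are from that table, counted from 1. Neither immunoglobulin heavy or kappa segments nor mitochondrial genes appeared among the symbols (0 of each), and the symbols of some list members, such as Xist, Ighm and Mx1, were not analysed here. Library totals were 19692505 and 19758671 estimated reads for wild type and 19581575 and 19605800 for knockout. On these unscaled totals, 3 reads, the limit a count of 0 allows, equal 0.152 to 0.153 CPM. Such limits cover counting error only. The values were rounded to whole numbers before testing.

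The main test was edgeR 4.0.16's quasi-likelihood test (R 4.3.3) with TMM normalization, filterByExpr (minimum count 10), no covariate and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. CPM values are scaled by the TMM factors. Of the symbols, 12123 were tested and 4490 fell below the filter. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so no such test was run on single genes. Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 on log2 CPM with a prior count of 2, with adjustment over 30 lists of at least 5 tested genes, and beside it with camera at an estimated correlation, with camera on ranks and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. No list was called with an estimated correlation. This includes lists whose estimate lay below the preset 0.01, such as neutrophil genes (-0.014) and p53 targets (-0.055). For such lists, correlation among genes does not explain the loss of the call. The 35 lists, the rule for named genes and the alternatives were chosen before the data were examined, except where said otherwise, and most named genes were then taken by that rule from their values.

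The genes named in the text follow a rule: Anp32b, Anp32a, Anp32e, Set, Spi1, Mycn and Myc whatever their values. The 10 largest changes in each direction among called genes with a mean of at least 5 CPM in the higher group and separated libraries, without receptor segments, sex-linked or predicted genes. And in each list the 3 called members with the smallest p, or the most abundant member where none was called. Some genes that the rule selects are not reported here. The lists cover the Anp32 family and Set, pro-B and pre-B cells, mature B cells, B lineage transcription factors, PU.1-regulated genes of B cells and of myeloid cells, pre-BCR and BCR signalling, IL-7 receptor and JAK-STAT signalling, MYC targets, mitosis, DNA replication, cell cycle inhibitors, p53 targets, apoptosis, B-ALL genes, interferon-stimulated genes, class I and class II histocompatibility genes, glycolysis, the integrated stress response, immediate early genes, adhesion receptors, ribosomal proteins, oxidative phosphorylation, and markers of neutrophils, monocytes, erythroid, T, NK, megakaryocyte, plasma and plasmacytoid dendritic cells, stem cells, stromal cells and sex.

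Transcript length was the median over the protein-coding GENCODE transcripts of a gene, for genes of at least 5 CPM in wild type. The alternatives were the replicate number as a block, DESeq2 1.42.0, limma-voom, RLE and upper-quartile normalization, no filter and a filter of 10 CPM in 2 libraries, omission of haemoglobin genes, a fold change of at least 2, and leaving out each library in turn, where the lone library is assumed to vary like the pair of the other genotype. Added after seeing the data were an assumed biological coefficient of variation of 0.1 and lists without genes of other cell types. The procedure was tested on simulated counts drawn from the real means and library sizes, with 11959 tested genes. The changed genes were picked only among those with a mean of at least 5 CPM. Of these, 66% changed 1.25-fold, 98% changed 1.5-fold and 100% changed 2-fold or 4-fold were recovered. These shares do not hold for genes of lower level. Among 193 calls, 11 (5.7%) were false. This was a single draw, with 50 genes changed at each fold and the same spread for both genotypes. In the real data, 23.6% of the tested genes were called. The wild-type pair also varied more than the knockout pair (chi-square per degree of freedom 5.56 against 2.14). The 5.7% is therefore not the error rate of the real calls. A list of 20 genes shifted 1.25-fold was called, and 0 of 20 unchanged lists were. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely. In the real lists the estimated correlation reached 0.74 (ribosomal protein genes).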

Results

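Gene expression was measured by RNA-seq in GFP+ bone marrow cells of mouse recipients that had been given B220+ bone marrow cells transduced with N-myc. The labels call these cells N-myc-induced B-ALL (B-cell acute lymphoblastic leukaemia) cells of the C57BL/6 strain. The donor cells were either Anp32b+/+ (wild type) or Anp32b-/- (knockout), with 2 libraries per genotype and 4 in all. Anp32b encodes a nuclear acidic protein of the ANP32 family, several members of which bind histones. The comparison asks which transcripts differ when leukaemia arises from cells without Anp32b, and the series title names the transcription factor PU.1, the product of Spi1. The libraries held 19692505 and 19758671 estimated reads for wild type, and 19581575 and 19605800 for knockout. The files list 16613 gene symbols. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Replicates differed by more than sampling noise (chi-square per degree of freedom 5.56 between the wild-type libraries and 2.14 between the knockout libraries), and less than libraries of different genotype did (19.6 to 20.99).

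Anp32b was strongly reduced in the knockout libraries, as their labels state. Its normalised read count was 814 ± 56.0 CPM (library-scaled counts, SD, n = 2) in wild type and 72.5 ± 2.68 (SD, n = 2) in knockout, 11.2-fold lower (log2 fold change -3.49, SE 0.07, edgeR adjusted p = 2.27e-13). The single libraries were at 774 and 853 CPM against 74.4 and 70.6 CPM. The gene lies on chromosome 4 at 46450926 to 46472657 (GRCm38), and counts per gene do not show which of its exons the remaining reads cover. The related genes Anp32a (log2 fold change 0.05, adjusted p = 0.571) and Anp32e (-0.05, adjusted p = 0.572) did not pass the edgeR test, and nor did Set (0.15, adjusted p = 0.0717). So 1 of the 4 genes of this list was called, and 2 when adjusted over the list alone, Set being the other. Set was also called with the replicate number as a block. Anp32a was called without wild-type replicate 2 (0.12, adjusted p = 0.0493), and Set was called without it too (0.21, adjusted p = 0.00229).

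Spi1, on chromosome 2 at 91082374 to 91115759, was at 65.3 ± 4.20 CPM in wild type and 66.4 ± 2.5 CPM in knockout (SD, n = 2 each). The log2 fold change was 0.02 (SE 0.06, 95% interval -0.11 to 0.16, edgeR adjusted p = 0.833), so no difference in Spi1 RNA was detected and the interval leaves room for a small change in either direction. The sign of this value was not stable: it was -0.0062 with upper-quartile normalization, -0.044 without wild-type replicate 2 and -0.014 without knockout replicate 2. Mycn, the driver gene of this leukaemia, was at 935 ± 110 CPM in wild type and 933 ± 16.4 CPM in knockout (log2 fold change -0.0033, edgeR adjusted p = 0.978). The counts do not separate the introduced N-myc from the endogenous gene. Its wild-type libraries lay apart, and Mycn was called higher in knockout without wild-type replicate 1 (0.12, adjusted p = 0.0314) and lower without wild-type replicate 2 (-0.12, adjusted p = 0.0358). Myc, the related oncogene, fell from 83.0 ± 5.29 to 34.4 ± 1.09 CPM (log2 fold change -1.27, SE 0.07, adjusted p = 8.90e-09).

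**Figure D1:**
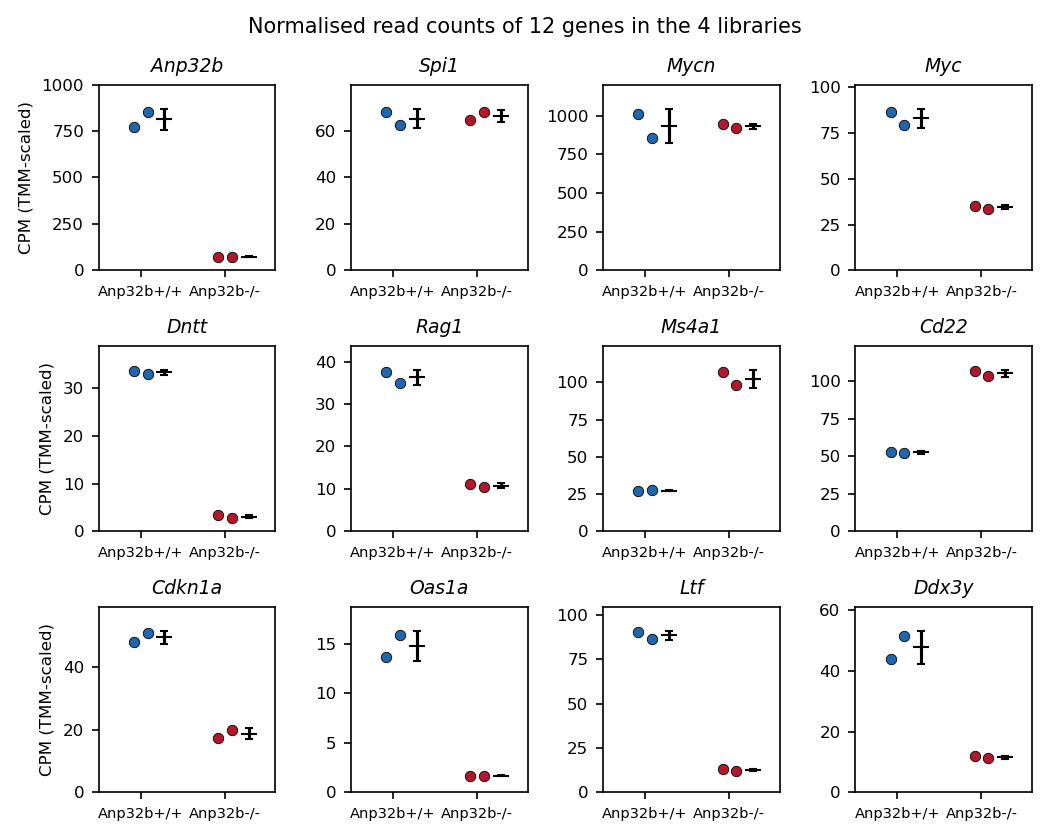
Normalised read counts (CPM, linear axes from 0) of 12 genes in each library, with wild type (Anp32b+/+) in blue and knockout (Anp32b-/-) in red. The black marks show the mean ± SD of the 2 libraries of a group. Anp32b falls from a mean of 814 to 72.5 CPM, while Spi1 stands at 65.3 and 66.4 CPM.

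Beyond Anp32b, and leaving out receptor segments, the sex-linked list and predicted genes such as Gm4779, the largest rises among genes of at least 5 CPM were those of Cd6, Xlr3b, Ptprd, Echdc2, Large2, Kcnk1, Slc8a1, Ugt2b35, Neb and Zbtb32, and the largest falls were those of Trpc4, Fam177a2, Col6a6, Pcp4l1, Steap4, Cdhr2, Zfp966, Mmrn1 and Xlr4a. Echdc2 rose from 3.62 ± 0.20 to 38.5 ± 0.52 CPM (log2 fold change 3.41, SE 0.10, edgeR adjusted p = 2.10e-11). Kcnk1, a potassium channel gene, rose from 1.03 ± 0.04 to 9.78 ± 0.40 CPM (3.24, SE 0.19). Ptprd, a receptor tyrosine phosphatase gene, rose by 3.65 (SE 0.25) to 31.3 ± 11.0 CPM, with a wide spread between the knockout libraries. Cd6, a surface receptor best known from T cells, had 5 reads in the wild-type libraries and 406 in the knockout libraries, a ratio of 83.1 with a 95% counting interval of 35.3 to 257. Its wild-type reads were 1 and 4, and the log2 fold change was 7.53 without wild-type replicate 2 and 5.65 without wild-type replicate 1. Steap4, a metalloreductase gene, fell from 20.4 ± 0.79 to 1.24 ± 0.44 CPM (-4.04, SE 0.17). Cdhr2 fell from 19.1 ± 0.90 to 1.24 ± 0.07 CPM (-3.94, SE 0.15) and Mmrn1 from 13.3 ± 0.42 to 0.93 ± 0.0039 CPM (-3.83, SE 0.18). Trpc4 had 243 reads in wild type and 6 in knockout, a ratio of 39.6 (95% counting interval 17.9 to 109). Xlr3b, Xlr4a, Fam177a2, Zfp966 and Ugt2b35 belong to families of near-identical copies between which reads can be split, so their values are uncertain. Over the leave-outs the log2 fold change of Xlr3b ran from 4.79 to 10.96, that of Fam177a2 from -11.66 to -3.41 and that of Zfp966 from -9.67 to -2.86. Zfp966 was not called without knockout replicate 2 (adjusted p = 0.0818), with no filter (0.117) or with DESeq2 (0.327), and Fam177a2 was not called with DESeq2 (0.325). Intervals of this kind cover counting error only.

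Of 12123 tested genes, edgeR's quasi-likelihood test called 2856 at an adjusted p under 0.05: 1323 were higher and 1533 lower in knockout. At a fold change of at least 2, 157 were higher and 473 lower. The values of all 4 libraries separated the genotypes for 60.5% of the tested genes, where chance gives 33.3%. The common biological coefficient of variation was 0.0409. The counts of calls differed between settings: with DESeq2 they were 729 and 847, without knockout replicate 1 they were 588 and 867, and without knockout replicate 2 they were 372 and 579. With no filter on low counts they were 547 and 744, and with upper-quartile normalization the share of calls that were lower went from 53.7% to 63.0%. Fits without a knockout library take their spread from the wild-type pair, which varied more (chi-square per degree of freedom 5.56 against 2.14). A call lost in such a fit, here and below, does not show that the omitted library carried it. Among lists that camera did not call, fry also called DNA replication, IL-7 receptor, class I, T cell, plasma cell and stress response genes lower. It called glycolysis, adhesion and erythroid genes higher (fry adjusted p from 0.0129 to 0.0395 over these lists).

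**Figure D2:**
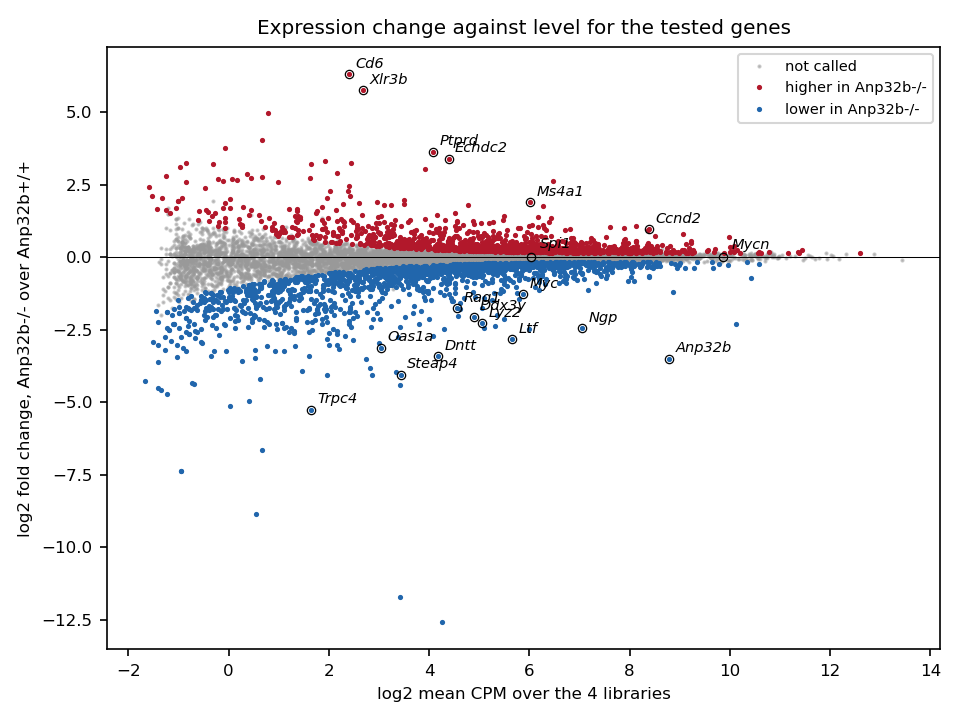
Log2 fold change of knockout over wild type (vertical axis) against the log2 mean CPM of the 4 libraries (horizontal axis) for the tested genes, with red for called higher, blue for called lower and grey for not called. Circles mark named genes. The 152 genes lower by at least 4-fold outnumber the 38 higher by at least 4-fold, and Mycn and Spi1 lie near 0. Genes with no reads in a group are drawn at fitted values that depend on the prior count.

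Genes of early B cell stages were lower in the knockout libraries, in which neutrophil genes (median -2.0) and Y-linked genes (median -2.08) fell too. Dntt, which encodes the terminal transferase that adds nucleotides at V(D)J joints, fell from 33.2 ± 0.57 to 3.11 ± 0.39 CPM (log2 fold change -3.41, SE 0.11, edgeR adjusted p = 5.85e-11). The recombinase genes Rag1 (-1.75, SE 0.09) and Rag2 (-1.26, SE 0.11) fell as well. Of 18 tested pro-B and pre-B cell genes, 13 fell and none rose (13 and 1 when adjusted over the list alone), and camera called the list lower (median log2 fold change -0.37, adjusted p = 5.75e-06, adjusted p = 0.266 with an estimated correlation). Vpreb1, a surrogate light chain gene, moved little by comparison (-0.37, SE 0.05).

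Ms4a1, Cd22 and 4 other genes of mature B cells rose. Ms4a1, which encodes CD20, rose from 27.3 ± 0.44 to 102 ± 6.16 CPM (1.91, SE 0.07, edgeR adjusted p = 1.09e-10). Cd22, an inhibitory receptor gene, rose from 52.6 ± 0.76 to 105 ± 2.36 CPM (1.00, SE 0.06), and Tnfrsf13c, which encodes the BAFF receptor, rose by 0.57 (SE 0.05). Of 13 tested mature B cell genes, 6 rose and 1 fell (7 and 1 when adjusted over the list alone). Camera called the list higher (median 0.28, adjusted p = 0.0451, adjusted p = 0.478 with an estimated correlation). This call was lost in each of the leave-outs. The adjusted p was 0.108 without wild-type replicate 1, 0.123 without wild-type replicate 2, 0.119 without knockout replicate 1 and 0.204 without knockout replicate 2. The list was also not called on ranks (0.134) or with no filter (0.0593). Of 20 B lineage transcription factors, 8 fell and 3 rose (11 and 3 when adjusted over the list alone), without a list call (camera adjusted p = 0.0501). The list was called lower with RLE normalization (adjusted p = 0.0499), with a filter of 10 CPM (0.0242) and without wild-type replicate 2 (0.0106), but not with an estimated correlation (adjusted p = 0.609). Foxo1 (-0.87, SE 0.05), Bach2 (-0.73, SE 0.07) and Erg (-0.69, SE 0.06) were the leading members. In pre-BCR and BCR signalling, 5 of 21 genes rose and 8 fell (5 and 9 when adjusted over the list alone), without a list call (camera adjusted p = 0.630): Ptpn6, which encodes the phosphatase SHP-1, rose by 0.67 (SE 0.05). For IL-7 receptor and JAK-STAT signalling, 2 of 17 genes rose and 4 fell (3 and 4 when adjusted over the list alone, camera adjusted p = 0.499), Pim1 (-0.29), Jak1 (-0.24) and Jak2 (-0.34) among them. These 3 calls were lost without knockout replicate 2 (adjusted p = 0.0979, 0.138 and 0.265), and that of Jak1 also without knockout replicate 1. Y-linked genes (median -2.08) and neutrophil genes (median -2.0) were lower in the same knockout libraries.

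PU.1-regulated genes of myeloid cells were lower in the knockout libraries, and those of B cells were not called as a list. Of 20 tested PU.1-regulated genes of myeloid cells, 12 fell and 1 rose (14 and 2 when adjusted over the list alone), and camera called the list lower (median -0.93, adjusted p = 5.67e-05, adjusted p = 0.266 with an estimated correlation, adjusted p = 0.0796 with a filter of 10 CPM). Lyz2, the lysozyme gene, fell from 55.3 ± 0.68 to 11.6 ± 0.10 CPM (-2.26, SE 0.08, edgeR adjusted p = 8.22e-11). Cybb, an NADPH oxidase gene, fell from 37.7 ± 0.19 to 14.2 ± 0.17 CPM (-1.41, SE 0.08). Itgam, which encodes CD11b, fell from 8.40 ± 0.17 to 2.26 ± 0.43 CPM (-1.89, SE 0.17). Of these 20 genes, 6 also stand in lists of other cell types, and neutrophil genes fell in the same libraries (median -2.0). Without the genes of other cell types, an alternative chosen after seeing the data, the list was called lower (adjusted p = 0.0257), but its remaining members, such as Itgam and Cybb, are also expressed by neutrophils. Of 18 PU.1-regulated genes of B cells, 7 rose and 2 fell (7 and 2 when adjusted over the list alone), without a camera call (median 0.05, adjusted p = 0.130), though fry, which tests a list by itself, called it higher (adjusted p = 0.0174). Ms4a1 and Cd22 led this list too, and Spib, whose product is related to PU.1, rose from 281 ± 0.0052 to 349 ± 6.88 CPM (0.31, SE 0.05), a call lost without knockout replicate 2 (adjusted p = 0.0739).

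Most of the p53 target genes and 4 of the cell cycle inhibitors fell in the knockout libraries. Cdkn1a, which encodes the inhibitor p21, fell from 49.6 ± 2.11 to 18.7 ± 1.75 CPM (-1.41, SE 0.08, edgeR adjusted p = 1.64e-08), and the antiproliferative genes Btg1 and Btg2 fell by 0.77 (SE 0.05) and 0.44 (SE 0.06) on the log2 scale. Of 12 cell cycle inhibitors, 4 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.00573, adjusted p = 0.387 with an estimated correlation). Of 18 p53 target genes, 12 fell and none rose, also when adjusted over the list alone (median -0.59, camera adjusted p = 5.75e-06, adjusted p = 0.266 with an estimated correlation), Phlda3 (-1.02, SE 0.10) and Trp53inp1 (-0.64, SE 0.06) after Cdkn1a. In a second list of p53 targets, drawn up later, 3 of 14 tested genes rose and 2 fell. The mitosis genes (2 of 20 rose, 1 fell, also when adjusted over the list alone, camera adjusted p = 0.943) and DNA replication genes (1 of 24 rose, 2 fell, also when adjusted over the list alone, adjusted p = 0.130) were not called as lists. The median of the mitosis genes was -0.02 and the camera direction upward, so the sign is open. The calls of Bub1b (0.18), Cenpe (-0.20), Ube2c (0.18), Gins2 (-0.29), Rrm2 (-0.21) and Ccne1 (0.21) were lost without knockout replicate 1 and without knockout replicate 2. Y-linked genes (median -2.08) and neutrophil genes (median -2.0) were lower in these knockout libraries as well.

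Among apoptosis regulators, Bcl2l1, which encodes the survival protein BCL-XL, fell from 61.4 ± 0.91 to 27.5 ± 0.07 CPM (-1.16, SE 0.07, edgeR adjusted p = 1.57e-08). Of 19 tested regulators, 2 rose and 6 fell (3 and 7 when adjusted over the list alone), among them Bmf, a pro-apoptotic gene (camera adjusted p = 0.0679, and 0.0316 without wild-type replicate 1). Bmf (-0.92) was not called without knockout replicate 2 (adjusted p = 0.0520). Of 28 B-ALL tumour suppressors and oncogenes, 1 rose and 9 fell (2 and 11 when adjusted over the list alone), and camera called the list lower (median -0.11, adjusted p = 0.0220, adjusted p = 0.478 with an estimated correlation). Its called members with the smallest p were Myc, Btg1 and Erg. The call of the list was lost without wild-type replicate 1 (adjusted p = 0.0782) and without knockout replicate 2 (0.137). MYC target genes were called higher: 8 of 30 rose and 1 fell (9 and 1 when adjusted over the list alone, median 0.11, camera adjusted p = 0.0128, adjusted p = 0.478 with an estimated correlation). Ccnd2, the cyclin D2 gene, rose from 227 ± 0.49 to 441 ± 11.7 CPM (0.96, SE 0.05). Tfrc, the transferrin receptor gene, fell by 0.32 (SE 0.05) on the log2 scale, a call lost without knockout replicate 2 (adjusted p = 0.0755). Ppan rose by 0.24 (SE 0.05), a call lost without either knockout replicate (highest adjusted p = 0.117). The list call was lost without wild-type replicate 1 (adjusted p = 0.103) and without knockout replicate 2 (0.0540). Neutrophil genes (median -2.0) and Y-linked genes (median -2.08) fell in the knockout libraries beside these lists.

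Most interferon-stimulated genes fell in the knockout libraries. Oas1a, an antiviral oligoadenylate synthetase gene, fell from 14.7 ± 1.54 to 1.70 ± 0.01 CPM (-3.11, SE 0.16, edgeR adjusted p = 6.34e-09). Rtp4 fell from 8.65 ± 0.60 to 1.31 ± 0.40 CPM (-2.71, SE 0.20) and Ifi27l2a from 32.6 ± 5.97 to 11.6 ± 0.23 CPM (-1.49, SE 0.12). Of 23 tested genes, 21 fell and none rose (23 and 0 when adjusted over the list alone), with a median log2 fold change of -1.72 (camera adjusted p = 2.47e-13, adjusted p = 0.266 with an estimated correlation). The neutrophil genes (median -2.0) and the Y-linked genes (median -2.08) fell in the same libraries. Class II major histocompatibility genes were called higher, with 6 of 10 up and 2 down, also when adjusted over the list alone (median 0.36, camera adjusted p = 0.0168, adjusted p = 0.478 with an estimated correlation). Cd74, the invariant chain gene, rose from 200 ± 8.01 to 280 ± 0.62 CPM (0.49, SE 0.05) and H2-DMb2 from 10.4 ± 0.07 to 22.5 ± 1.70 CPM (1.10, SE 0.10), while H2-Oa fell by 0.93 (SE 0.15) on the log2 scale. The list call was lost without knockout replicate 2 (adjusted p = 0.0545). Class I genes were not called (2 of 10 fell, also when adjusted over the list alone, camera adjusted p = 0.231). H2-D1 (-0.17) and Tap1 (-0.17) were the 2, and both were lost without either knockout replicate (highest adjusted p = 0.327 for each).

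Immediate early and stress genes were mixed. Fosb rose from 391 ± 29.9 to 687 ± 26.6 CPM (0.81, SE 0.06, edgeR adjusted p = 2.07e-07). Klf2, a regulator of lymphocyte trafficking, rose from 226 ± 7.53 to 438 ± 3.78 CPM (0.96, SE 0.05) and Fos from 194 ± 4.08 to 274 ± 5.51 CPM (0.50, SE 0.05). Of 17 tested genes, 7 rose and 3 fell (8 and 4 when adjusted over the list alone, camera adjusted p = 0.10). The list was called higher with a filter of 10 CPM (adjusted p = 0.0227) and with fry (0.0395). Of 14 amino acid and integrated stress response genes, 2 rose and 3 fell (5 and 4 when adjusted over the list alone, camera adjusted p = 0.717): Trib3 fell by 1.02 (SE 0.14), and Asns, the asparagine synthetase gene, rose by 0.33 (SE 0.07), a call lost without knockout replicate 2 (adjusted p = 0.0815). The call of Sesn2 (-0.81) was lost there and without knockout replicate 1 (highest adjusted p = 0.0675). Of 15 adhesion and homing receptors, 6 rose and 2 fell (6 and 3 when adjusted over the list alone, camera adjusted p = 0.404). S1pr1, a sphingosine phosphate receptor gene, rose by 0.83 (SE 0.10), Itga6 rose by 0.53 (SE 0.08) and Itgal fell (-0.63, SE 0.08). The median of this list was -0.04 while its mean was 0.02. Glycolysis genes were not called (5 of 17 rose and none fell, 8 and 2 when adjusted over the list alone, camera adjusted p = 0.0760, and 0.0454 with no filter). The calls of Eno1 (0.26), Aldoa (0.25) and Slc2a1 (0.29) were lost without either knockout replicate (highest adjusted p = 0.127, 0.157 and 0.101).

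Most ribosomal protein and oxidative phosphorylation genes did not pass the test. Of 78 ribosomal protein genes, 4 rose and 2 fell (1 and 1 when adjusted over the list alone, median 0.07, camera adjusted p = 0.0153, adjusted p = 0.740 with an estimated correlation). Of 75 oxidative phosphorylation genes, 11 rose and 2 fell (9 and 2 when adjusted over the list alone, median 0.05, camera adjusted p = 0.0428, adjusted p = 0.740 with an estimated correlation). Without wild-type replicate 1 both lists turned to the lower direction and were not called (adjusted p = 0.841 for both), and without knockout replicate 2 they were not called (0.146 and 0.294). Both calls were also lost with a filter of 10 CPM (adjusted p = 0.0796 and 0.0859) and with fry (0.555 for both), and that of oxidative phosphorylation with upper-quartile normalization (0.0543). Across 9273 genes, which are not independent replicates, the log2 difference of wild-type replicate 2 from 1 had a Spearman rho of -0.30 with transcript length. It was -0.14 for knockout replicate 2 from 1 and -0.10 for knockout from wild type. Rpl35 (0.25) and Ndufb10 (0.30) were not called without knockout replicate 2, and Rpl29 (0.20), Ndufa3 (0.23) and Atp5d (0.21) without either knockout replicate (adjusted p up to 0.187, 0.125, 0.402, 0.180 and 0.207). The low count of Rps6 (50.6 ± 2.15 CPM in wild type, log2 fold change -0.39), a gene with many processed copies, is uncertain, and its call was lost without knockout replicate 2 (adjusted p = 0.0569).

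Among markers of other bone marrow cells, the neutrophil, monocyte and plasmacytoid dendritic cell lists were called lower. Neutrophil genes fell in 17 of 18 cases and none rose (18 and 0 when adjusted over the list alone), with a median of -2.0 (camera adjusted p = 1.13e-13, adjusted p = 0.266 with an estimated correlation). Ngp fell from 225 ± 11.5 to 41.6 ± 1.70 CPM (-2.44, SE 0.06, edgeR adjusted p = 6.50e-12). Ltf, the lactoferrin gene, fell from 88.5 ± 2.64 to 12.6 ± 0.71 CPM and Lcn2, the lipocalin 2 gene, from 66.6 ± 0.50 to 12.9 ± 0.49 CPM. Monocyte and macrophage genes were called lower as a list (4 of 13 fell, none rose, 7 and 0 when adjusted over the list alone, median -0.51, camera adjusted p = 0.00374, adjusted p = 0.478 with an estimated correlation), with Lyz2 in front. The calls of Csf1r (-1.0) and F13a1 (-1.15) were lost without knockout replicate 2 (adjusted p = 0.0601 for Csf1r). F13a1 was also lost without wild-type replicate 1 and without knockout replicate 1 (highest adjusted p = 0.155). Plasmacytoid dendritic cell genes were called lower (3 of 7 fell, also when adjusted over the list alone, median -0.93, camera adjusted p = 0.0168, adjusted p = 0.478 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.0777). Of these 7 genes, 5 stand in other lists. Siglech (-1.36) was not called without knockout replicate 1 (adjusted p = 0.0691), and Runx2 (-0.93) was not called in any of the 4 leave-outs (highest adjusted p = 0.163), while Tcf4 (-0.40, SE 0.07) kept its call in all 4. Erythroid genes were not called (1 of 12 rose, Car1, with 14 and 43 reads, camera adjusted p = 0.185). The call of Car1 was lost without wild-type replicate 2 and without knockout replicate 2 (highest adjusted p = 0.233). T cell genes were not called either (3 of 8 rose, 3 fell, adjusted p = 0.604). Lat rose by 1.00 (SE 0.07), while Tcf7 (-1.40, SE 0.13) and Cd4 (-1.61, SE 0.27) fell. The plasma cell genes (2 of 7 rose, 4 fell, adjusted p = 0.236) held Jchain (-2.03, SE 0.12) and Irf4 (-0.30, lost without knockout replicate 2, adjusted p = 0.0955), and Derl3 (0.75, lost without knockout replicate 1, adjusted p = 0.0904). The stem and progenitor genes (0 of 5 called, camera adjusted p = 0.0779) had Ly6a at 5.06 and 4.45 CPM, and the list was called lower without knockout replicate 1 (adjusted p = 0.00574). Smaller lists were only described in the main test. With no filter, the NK cell list reached 9 tested genes and camera called it lower (adjusted p = 0.00247). The megakaryocyte and stromal lists were not called there (adjusted p = 0.562 and 0.317). The NK cell list was also called lower in the leave-outs where it reached 5 tested genes. Of the NK cell genes, 2 of 4 fell: Klrb1c, with 103 and 11 reads, and Nkg7, which was called in 1 leave-out. Of the others, 0 of 2 megakaryocyte genes were called (Gp1ba at 0.96 and 0.75 CPM), and of 3 stromal and endothelial genes Sparc fell (-2.43, SE 0.38). The 4 Y-linked genes of the sex-linked list all fell (median -2.08), among them Eif2s3y (-2.12, SE 0.09), Ddx3y (-2.04, SE 0.10) and Kdm5d (-2.29, SE 0.11), while Gm52481, a tested Y chromosome gene outside the list, rose (0.80, SE 0.13). Xist was not analysed here.

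**Figure D3:**
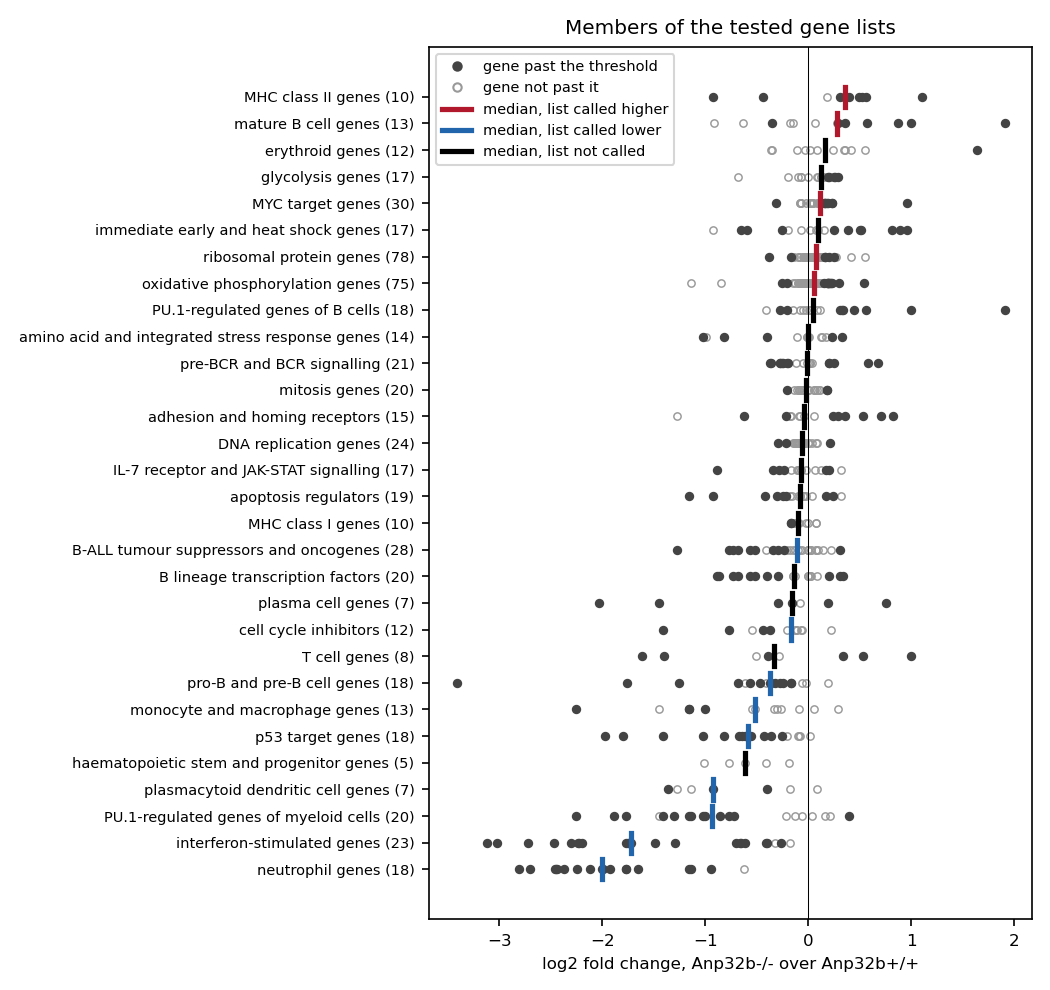
Log2 fold change of knockout over wild type (horizontal axis) for each tested member of the gene lists of at least 5 tested genes (rows, number tested in brackets). Filled points passed the threshold, and bars mark list medians, red or blue for lists camera called higher or lower. The neutrophil (-2.0) and interferon-stimulated (-1.72) lists have the lowest medians and class II genes (0.36) the highest.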

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

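The direction and call of Anp32b held in all alternatives run (log2 fold change -3.56 to -3.42 over the leave-outs). Spi1 was not called in any alternative. Its sign turned with upper-quartile normalization (-0.0062), and over the leave-outs its value ran from -0.044 to 0.0915. The counts of genes higher and lower, 1323 and 1533 in the main test, were 729 and 847 with DESeq2, 547 and 744 with no filter on low counts, 157 and 473 at a fold change of at least 2, and 441 and 915 with an assumed coefficient of variation of 0.1, an alternative chosen after seeing the data, where 67.5% of calls were lower. Over the leave-outs they ran from 372 to 1676 higher and 579 to 1712 lower, with the lowest values without knockout replicate 2. Upper-quartile normalization gave 1039 and 1767, with 63.0% lower against 53.7%. There the median log2 fold change of the tested genes was -0.028, against 0.0021 in the main test. Values thus shifted downward as a set, that of Spi1 among them. The cause of the other differences in counts was not tested. All 1576 DESeq2 calls were among the main calls. The differences between library 1 and library 2 of the genotypes had r = 0.03 over 12123 genes, and 0.05 over 11239 genes above 1 CPM. The replicate numbers thus gave little sign of pairing, but a shared animal, day or batch is not excluded. Both differences ran the same way with transcript length (Spearman rho -0.30 in wild type and -0.14 in knockout). The fit with the replicate block called 1644 and 1779 genes and 13 lists, without the mature B cell list (camera adjusted p = 0.0810).

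The 14 lists called became 0 with an estimated correlation, where camera gave unadjusted p values down to 0.0135, 23 with fry and 13 on ranks, and ran from 9 (without knockout replicate 2) to 15 over the leave-outs. The 9 and the 15 lists each include the NK cell list, which was too small for the main test. With the estimated correlation, the unadjusted camera p of neutrophil genes went from 3.78e-15 to 0.0135, at an estimate of -0.014. That of p53 targets went from 6.34e-07 to 0.0327, at -0.055. Both estimates lay below the preset 0.01, so correlation among genes does not explain these losses. Ribosomal protein genes, at 0.74, are a different case. Otherwise the cause was not tested. Mycn turned sign with the replicate block (0.00138), limma-voom (0.0016) and no filter (0.000318), and over the leave-outs it ran from -0.12 to 0.12 (0.015 without knockout replicate 2). Anp32a turned without wild-type replicate 1 (-0.018, leave-outs up to 0.12) and Anp32e without wild-type replicate 2 (0.011, leave-outs down to -0.11). The 109 genes counted next are all named genes other than Anp32b and Spi1. They include Mycn, Anp32a, Anp32e and others that had no call to lose. Of 109 further named genes, 13 lost their call with DESeq2, 16 with no filter, 28 with the assumed variation, 51 at a fold change of at least 2, and 2, 3, 23 and 34 without wild-type replicate 1, wild-type replicate 2, knockout replicate 1 and knockout replicate 2. Depth limits genes near 0.153 CPM, the level of 3 reads before TMM scaling.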

Other observations

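The genes in this paragraph were chosen after their values were seen. The D-type cyclins moved apart: Ccnd3, which pre-B cells use for proliferation, fell from 647 ± 11.5 to 283 ± 0.72 CPM (SD, n = 2 each, log2 fold change -1.19, SE 0.05, edgeR adjusted p = 8.32e-10), while Ccnd1 rose from 14.1 ± 0.38 to 32.8 ± 0.65 CPM (1.22, SE 0.08) beside Ccnd2. Single genes that rose included S100a6, from 24.7 ± 3.46 to 152 ± 0.24 CPM (2.62, SE 0.08), Ahnak (1.81, SE 0.09), S100a4 (1.14, SE 0.08), Emp3 (1.10, SE 0.06), Lgals1 (1.06, SE 0.06), Lmna (2.10, SE 0.17) and Vim (0.51, SE 0.05). The lymphotoxin genes Lta (-1.5, SE 0.09) and Ltb (-1.78, SE 0.09) and the growth factor receptor gene Igf1r (-2.41, SE 0.18) fell. The neighbouring X-linked genes Gm4779 and 8030474K03Rik, at 101790332 and 101794554, had no reads in either knockout library. They were at least 249-fold and 138-fold lower against the level of 3 reads per library (0.154 CPM after TMM scaling).

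Of the tests that follow, those on the share of leukaemia cells, on interferon genes in neutrophils and on DNA around Anp32b were chosen after the result was seen. For the glucocorticoid, p53 and Anp32b tests, the requirement that a value lie beyond its spread was also added after the values were known. Without it, the glucocorticoid and Anp32b tests would have counted against their explanations. With it, they were left undecided.

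Neutrophil genes fell together in the knockout libraries (median -2.0). A higher share of leukaemia cells would lower every other cell type alike. Against this, the median of the erythroid list lay 2.16 above that of the neutrophil list. But erythroid genes were scarce (median 2.43 CPM in wild type, 1 of 12 called). The medians of NK (-1.38), plasmacytoid dendritic (-0.93), stem (-0.61), monocyte (-0.51), megakaryocyte (-0.39), T (-0.33) and stromal cell genes (-0.31) were all negative. Of these, camera called the monocyte and plasmacytoid dendritic lists lower. The NK, megakaryocyte and stromal medians rest on only 4, 2 and 3 tested genes. Of 8 T cell genes, 3 rose and 3 fell, and 0 of 5 stem cell genes were called. Whether a higher share of leukaemia cells contributed therefore stays open. A second list of neutrophil genes, fixed before its values were seen, had a median of -1.67 (13 of 15 fell), consistent with fewer neutrophils in the knockout samples. The most abundant neutrophil genes of the first list stood at 225 CPM (Ngp) and 108 CPM (S100a9) in wild type, and a GFP+ sort would remove most unlabelled neutrophils, so whether these are sorted bystanders or GFP+ cells stays open.

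Y-linked genes fell as well (median -2.08), though Gm52481, outside that list, rose (0.80, SE 0.13). X-linked partners that escape inactivation were higher, with a median of 0.44 (3 of 4 called: Kdm6a 0.54, Eif2s3x 0.44, Kdm5c 0.43, Ddx3x 0.15 was not), consistent with more female cells in the knockout samples. Fewer neutrophils carrying the Y-linked reads would not by themselves account for the higher X-linked partners. Eif2s3x rose from 277 ± 2.71 to 376 ± 6.77 CPM and Kdm5c from 153 ± 5.42 to 207 ± 0.92 CPM. Kdm6a rose from 39.8 ± 1.69 to 57.6 ± 2.42 CPM. Whether fewer neutrophils added to the Y-linked fall stays open. The lowest ratio of Ddx3y to Ddx3x in wild type was 0.0966. The ratios of Eif2s3y to Eif2s3x were 0.242 and 0.287, those of Kdm5d to Kdm5c 0.149 and 0.152, and those of Uty to Kdm6a 0.527 and 0.501. The last pair goes most against a small admixed share, but the ratios that male cells alone would give were not measured. The sex of donors and recipients is untested here.

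Interferon-stimulated genes fell by a median of 1.72 on the log2 scale. If fewer neutrophils carried these transcripts, none should fall by more than the neutrophil genes did: 2 of the 21 called genes, Oas1a and Zbp1, lay below the lowest neutrophil gene, yet the median of the called genes (-1.74) was within the spread of the neutrophil genes (-2.0, SD 0.55). The share from neutrophils and a lower interferon response of the leukaemia cells cannot be told apart with these values.

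Further tests left their questions open. A second list of p53 targets, with 14 tested, had a median of -0.13 (unadjusted p = 0.363 in limma's camera). Of these, Plxnb2 (0.56), Ercc5 (0.42) and Dyrk3 (0.31) rose and 2 fell, so lower p53 activity in the leukaemia cells was not shown by it. A list of other glucocorticoid-induced genes had a median of -0.024 with members in both directions, which decides nothing about Fkbp5 (0.97) and Tsc22d3 (0.94). Within 10 Mb of Anp32b, 18.7% of 107 tested genes were called (exact 95% interval 11.8% to 27.4%) against 23.5% elsewhere (one-sided Fisher's exact p = 0.904), so no excess from DNA of another strain was seen, though a small one is not excluded.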
